A study of Mus musculus with 12 samples.

How the data were processed

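RNA-seq of polyadenylated RNA was made from Cre-selected cortical nuclei of male pups at P0, P14 and P28, with 4 libraries per age. The deposited files were 3 tables of normalized counts, 1 per age, and per the labels the submitters' processing notes name DESeq2 and the mouse genome build mm10, without versions. The unit of the deposited values is signal, a normalized read count: the authors divided the reads of each gene by a single factor per library, and each age's table was normalized on its own. The aligner, the counting tool, the counted strand, the gene annotation and any filter on low counts are not given in the sources used here. Within the tolerance of 0.05 reads every value of each of the 12 columns was a whole multiple of that library's smallest step, so whole reads were recovered for all 12 libraries (for P0 replicate 1 the step was 1.005 and thus close to 1). The tables listed 27219, 28826 and 30150 genes at P0, P14 and P28, and 25834 were in all 3. The labels name P0 replicate 1 and P28 replicate 4 as merged libraries. Of the columns in the tables, 0 were without a matching sample.

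Separate normalization was undone as follows. Each column was divided by its own total over the 25834 shared genes, which removes the authors' factor, and the resulting CPM were scaled by a median-of-ratios factor estimated over all 12 libraries together (0.936 to 1.04). Genes at 1 or more scaled CPM in at least 4 libraries were kept (15734 genes), and log2(scaled CPM + 0.5) was analysed. Fold changes on this scale are understated for genes near the pseudocount. Differential expression was tested, two-sided, with limma (trend and robust, age as a factor with 3 levels, all 12 libraries, no block), and p was adjusted by Benjamini and Hochberg over the genes of a comparison, with 0.05 as the threshold. Since the replicate numbers pair no animals between ages, no pairing was used. Recovered reads per library were 13195973 to 16599217 at P0, 25486861 to 33611769 at P14 and 21569262 to 31215435 at P28, and the 10 most abundant genes took 2.28 to 3.95% of the reads of a library. For H2bc21 an exact two-sided permutation test of the 8 libraries was run beside limma. The code was tested on simulated data in which known genes were changed, and it recovered 25.4 to 31.3% of 1.5-fold, 62.7 to 73.1% of 2-fold and 92.4 to 98.5% of 4-fold changes, with 8, 8 and 6 false calls among 132, 137 and 137 calls.

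Lists fixed before the data were examined covered histone variants, other H2B genes, immature neuron and growth genes, axon guidance, presynaptic and postsynaptic genes, glutamate receptors, GABA-A receptors and chloride transport, voltage-gated channels, immediate-early genes, chromatin and DNA methylation, the perineuronal matrix, cholesterol synthesis, nuclear long noncoding RNAs, imprinted and growth genes, mitochondrially encoded genes and nuclear genes of oxidative phosphorylation. They also covered markers of excitatory and inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia and vessels, progenitor and cell cycle genes, and name families (ribosomal proteins, gamma protocadherins, Zfp zinc fingers, collagens). The 29 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, and fry was added after the data were seen. Members were matched by symbol, and 9 members, 7 of them mitochondrial, by Ensembl identifier. This second match was added after the data were seen, and without it the mitochondrial list would not have been among the 29. Genes named in the text were chosen by a rule set before the data were examined. It took the histone variants, the 6 largest rises and 6 largest falls of each step (3 and 3 for P28 against P0) among genes past the threshold with no overlap between the 4 and 4 libraries and a mean of at least 5 scaled CPM, up to 4 members of each list with the smallest adjusted p, each list's largest change against its majority, and the label checks. Genes named outside the rule are said to be so. Gene coordinates are those of RefSeq on GRCm38.p6, matched by symbol. The genome sequence and annotation at hand were of build NCBIM37, older than mm10, and served only for transcript length and GC content.

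Alternatives covered the pseudocount (0.1 and 2 CPM), the filter on low values, scaling (library total, upper quartile, quantile normalization, and the deposited values without rescaling), limma without trend or robust or on the 8 libraries of a comparison, edgeR quasi-likelihood, DESeq2 and limma on thinned reads, the genes of the tables compared, a replicate block, stricter thresholds, and leaving out each library or both merged libraries. Library weights, leaving out P14 replicates 2 and 4 together, and an estimated correlation without P14 replicate 2 were chosen after the data were seen. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes missing from any table (5645 of 31479) were left out of the tests over all 12 libraries, since a gene missing from a table cannot be told from a count of 0. No other data of the study were used here.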

Results

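The series profiled RNA from the nuclei of cortical cells of male mouse pups at postnatal days 0, 14 and 28 (P0, P14 and P28), with 4 biological replicates at each age and 12 libraries in all. The pups carried a single copy of NEX-Cre, which expresses Cre recombinase from the locus of Neurod6, a transcription factor of excitatory cortical neurons. They also carried a single copy of CAG-Sun1/sfGFP, a nuclear envelope protein fused to a green fluorescent protein that is made only after Cre acts. Tagged nuclei were purified by affinity (INTACT), and polyadenylated RNA was sequenced from stranded libraries. The labels place the series in a study of the histone variant H2BE in the brain. The library labels at P0 and P14 include WT, the usual short form of wild type, and those at P28 do not. These library labels do not say which locus WT refers to. The comparisons ask how nuclear transcripts of Cre-selected cortical cells, that of the H2BE gene among them, differed between the 3 ages. The libraries held 13195973 to 16599217 recovered reads at P0, 25486861 to 33611769 at P14 and 21569262 to 31215435 at P28. A count of 3 reads corresponded to 0.089 to 0.227 CPM (reads of a gene scaled to a common library total), and floors and intervals of this kind cover counting error only. Levels are given as scaled CPM, mean ± SD over 4 libraries, and changes as log2 fold changes ± SE with adjusted p from limma. Each age had its own deposited table, and whether the ages were handled together is not given in the sources used here.

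The label checks came out as follows. Neurod6, whose locus drives the Cre line, was at 282 ± 5.86 scaled CPM at P0, 62.5 ± 9.76 at P14 and 53.8 ± 3.31 at P28. It fell from P0 to P14 (log2 fold change −2.18 ± 0.10, adjusted p = 8.86e-10). The change from P14 to P28 did not pass the test (−0.20 ± 0.10, adjusted p = 0.186), although it passed in 3 of 30 alternatives, among them the fit without P14 replicate 2 (adjusted p = 0.0371, range over the alternatives 0.013 to 0.404). Sun1, whose coding sequence is part of the nuclear tag, was at 333 ± 46.2, 311 ± 27.1 and 439 ± 16.8 scaled CPM and rose from P14 to P28 (0.50 ± 0.10, adjusted p = 0.00574). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were read in all 12 libraries, at no less than 15.1 scaled CPM. Xist, the RNA of the inactive X chromosome, stood at 15.9 scaled CPM in P0 replicate 1 and at no more than 2.32 in any other library.

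The first principal component held 78.8% of the variance and separated P0 from the later ages. The second held 10.5% and set a single library, P14 replicate 2, apart from the rest. Log2 levels of that library correlated with the other P14 libraries at Pearson r of 0.944 to 0.962 across genes, which are not independent replicates. Every other library had a mean r of at least 0.976 with the libraries of its age. P14 replicate 2 was kept, and gene group counts or calls that moved by more than 1.5 times or changed side without it are given with the group for each of the 2 steps.

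**Figure D1:**
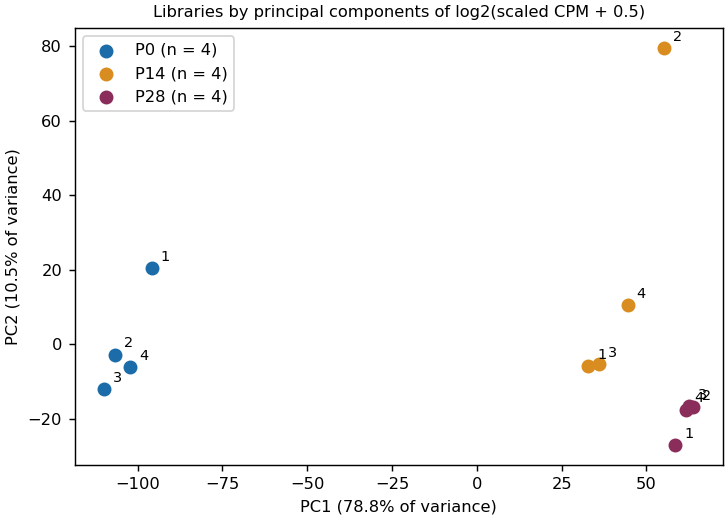
Principal component analysis of log2 levels of 15734 genes, with 1 point per library and colours for the 3 ages. The horizontal axis is the first component (78.8% of variance) and the vertical axis the second (10.5% of variance). The 4 P0 libraries lie at −109.9 to −95.8 on the first component, and P14 replicate 2 lies at 79.5 on the second.

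The transcript of the H2BE gene did not differ between ages by more than the replicate error. H2bc21 (older symbol Hist2h2be, ENSMUSG00000068854, chromosome 3, 96221072 to 96223738 on GRCm38.p6), which encodes H2BE, was at 9.96 ± 1.65 scaled CPM at P0, 10.4 ± 1.18 at P14 and 9.96 ± 1.25 at P28. These levels rest on 102 to 402 reads per library. The log2 fold change was 0.07 ± 0.15 from P0 to P14 (95% confidence interval −0.25 to 0.39, adjusted p = 0.691, exact permutation p = 0.657). From P14 to P28 it was −0.06 ± 0.15 (−0.39 to 0.26, adjusted p = 0.798, exact permutation p = 0.571). Between P0 and P28 it was 0.01 ± 0.15 (−0.32 to 0.33, adjusted p = 0.969, exact permutation p = 0.943). Each exact two-sided permutation test had 70 arrangements and a smallest possible p of 0.029, and the 3 values adjusted together were 0.943. Taken singly, the 3 intervals reached at most a rise of 1.31-fold and a fall to 0.765-fold. They cover replicate error under the main scaling only, and not the choice of scaling or a difference between the tables. From P0 to P14 the log2 fold change was 0.151 with scaling to the library total and 0.141 with quantile normalization. On the deposited values without rescaling across tables the P14 level was higher than that of P0 (log2 fold change 0.53, adjusted p = 0.00527), beside a shift of 0.47 in the median of all genes.

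Most other histone variant genes were lower after P0. From P0 to P14 vascular markers (median log2 fold change −2.93) and progenitor and cell cycle genes (−1.90) fell as well. How far a change in the mix of cells entered the falls of histone variant genes was not tested. Of 12 histone variant genes tested, 9 fell and 1 rose from P0 to P14 (camera adjusted p = 0.00787, adjusted p = 0.316 with an estimated correlation). Adjusted over the list alone, 10 fell and 1 rose. H3f3b, which encodes histone H3.3, fell from 700.2 ± 126 to 183 ± 41.9 scaled CPM (−1.94 ± 0.15, adjusted p = 1.07e-07). H3f3a, the other H3.3 gene, fell as well (−2.07 ± 0.28, adjusted p = 1.86e-05), with P14 replicate 2 at 8.79 scaled CPM below the other P14 libraries. Macroh2a2, a macroH2A gene, fell from 175 ± 9.36 to 35.7 ± 2.04 (−2.28 ± 0.09, adjusted p = 1.17e-10) and again to 25.6 ± 2.04 at P28 (−0.47 ± 0.09, adjusted p = 0.00264). The linker histone genes H1f0 (−1.31 ± 0.13, adjusted p = 1.17e-06) and H1f10 (−0.87 ± 0.26, adjusted p = 0.00881) fell in the same step. So did the centromeric Cenpa (−1.39 ± 0.19, adjusted p = 2.04e-05) and the H2A.Z genes H2az1 (−0.56 ± 0.10, adjusted p = 1.90e-04) and H2az2 (−1.21 ± 0.12, adjusted p = 8.25e-07). Macroh2a1 fell by a smaller amount (−0.44 ± 0.12, adjusted p = 0.00466), which became 0.04 on the deposited values without rescaling. The calls of H1f10 (−0.41, adjusted p = 0.159) and H2az1 (−0.081, adjusted p = 0.45) ended on those values. H2ax did not pass the test (−0.28 ± 0.13, adjusted p = 0.0641). It passed without P14 replicate 2 (adjusted p = 0.0279) or P28 replicate 1 (0.0423), with upper-quartile scaling (0.0471) and with library weights (0.0414), and was 0.20 on the deposited values (0.166). H2aj was the member that rose, from 10.4 ± 0.860 to 21.6 ± 1.53 (1.02 ± 0.11, adjusted p = 2.87e-06) and to 30.6 ± 3.54 at P28 (0.49 ± 0.11, adjusted p = 0.00974). From P14 to P28, 2 members rose and 1 fell (camera adjusted p = 0.982), or 2 and 2 adjusted over the list alone and also without P14 replicate 2. Both counts were 1 to 2 over the fits that left out 1 library. Deposited values without rescaling gave no call for H2aj in this step (adjusted p = 0.0602) and a fall of Macroh2a1 (−0.42, adjusted p = 0.0161). The rise of H1f0 in that step (0.42 ± 0.13, adjusted p = 0.0420) lost its call in 19 of 30 alternatives, among them each that left out 1 of the 4 P0 or 4 P28 libraries (range over the alternatives 0.00166 to 0.243). H3f3b had a log2 fold change of −0.46 ± 0.15 (adjusted p = 0.0503), and passed in 10 of 30 alternatives (range 0.0053 to 0.126). These were the 4 other scalings, a filter at a mean of 5 CPM, edgeR, DESeq2, library weights, and leaving out P0 replicate 3 or P0 replicate 4. Between P0 and P28, 9 of the 12 fell and 1 rose (camera adjusted p = 0.0131, adjusted p = 0.289 with an estimated correlation). H2ax was among those that fell (−0.37 ± 0.13, adjusted p = 0.0185), except in 4 of 30 alternatives (range 0.00231 to 0.514): without P28 replicate 3, without P28 replicate 4, without both merged libraries and on the deposited values. H2az1 did not pass on the deposited values in this comparison (adjusted p = 0.0859). Of 17 other H2B genes fixed as a list of replicative H2B genes, 3 were tested. The libraries were of polyadenylated RNA, so transcripts without a poly(A) tail could not be measured. A member that was not tested is therefore not shown to be silent. H2bc4 (1.58 ± 0.20) and H2bc6 (0.99 ± 0.29) rose from P0 to P14 and H2bu2 fell (−0.43 ± 0.13, adjusted p = 0.0104), and the list did not pass (camera adjusted p = 0.456). The fall of H2bu2 became 0.04 on the deposited values without rescaling. H2B genes are near-identical in sequence, and how reads shared between them were counted is not given in the sources used here.

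**Figure D2:**
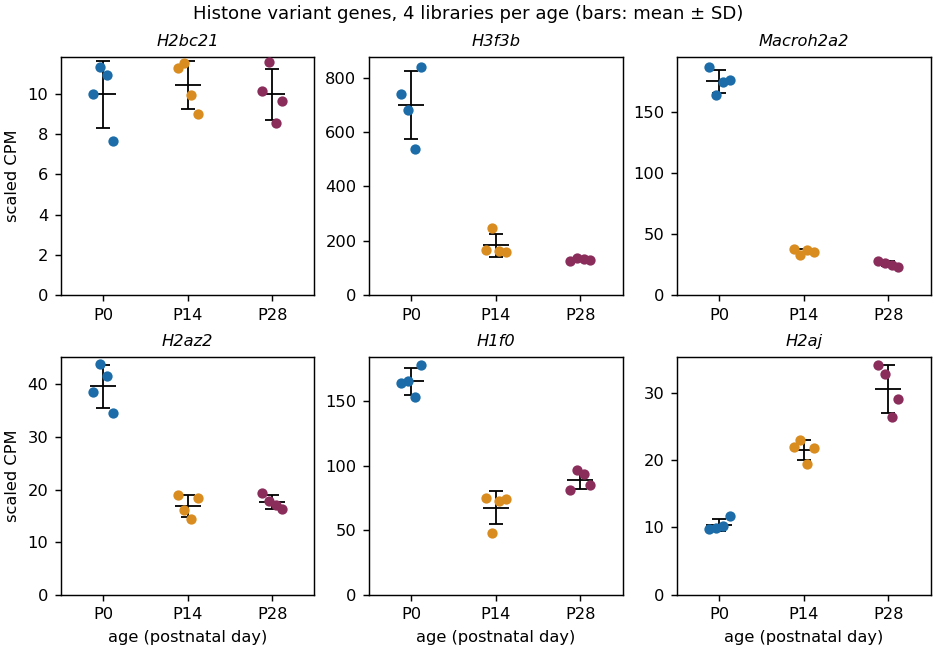
Scaled CPM (vertical axes, linear, from 0) of 6 histone variant genes at P0, P14 and P28 (horizontal axes), with 1 point per library and bars for the mean ± SD of 4 libraries. H2bc21 stays near 10 scaled CPM at each age, whereas H3f3b goes from a mean of 700.2 to 183 and Macroh2a2 from 175 to 35.7 between P0 and P14.

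Between P0 and P14 transcripts of neuron growth and axon guidance fell, and those of synapses, ion channels and myelin rose. These lists passed camera with the preset correlation, and 0 of the 29 lists passed with an estimated correlation (lowest adjusted p = 0.19). Markers of other cell types moved in the same step, with medians of −2.93 for vascular and 1.09 for microglia markers. Draxin, a secreted axon guidance protein (ENSMUSG00000029005, chromosome 4, 148098437 to 148131139), fell from 196 ± 13.7 to 1.85 ± 0.460 scaled CPM (−6.40 ± 0.15, adjusted p = 4.83e-12). Mobp, a myelin protein gene (ENSMUSG00000032517, chromosome 9, 120149742 to 120181488), went from 0.157 ± 0.219 to 150.0 ± 56.4 (7.80 ± 0.30, adjusted p = 1.37e-10). All 22 immature neuron and growth genes fell, and 21 of 22 presynaptic genes rose. In all, 10848 of 15734 genes changed, 5412 rising and 5436 falling. Of these 2510 rose and 2668 fell at least 2-fold, and 690 and 773 at least 4-fold.

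The other largest rises were those of Lamp5, a lysosomal membrane protein gene of cortical neurons (2.05 ± 0.674 to 161 ± 10.9 scaled CPM, 6.03 ± 0.17, adjusted p = 1.21e-11) and Slc30a3, the zinc transporter of synaptic vesicles (3.21 ± 0.831 to 175 ± 22.6, 5.59 ± 0.14, adjusted p = 6.87e-12). Ttr, which encodes transthyretin, went from 1.80 ± 2.84 to 101 ± 50.2 (6.01 ± 0.59, adjusted p = 9.44e-07). Hkdc1, a hexokinase-like gene, went from 0.373 ± 0.265 to 37.9 ± 4.96 (5.50 ± 0.19, adjusted p = 6.10e-11). Robo3, an axon guidance receptor, rose as well (5.46 ± 0.30, adjusted p = 3.87e-09). The other largest falls were those of the ubiquitin ligase gene Trim67 (−6.26 ± 0.16, adjusted p = 9.18e-12) and of Igfbpl1 (chromosome 4, 45809507 to 45826827), at −6.20 ± 0.18 (adjusted p = 1.25e-11). The polysialyltransferase gene St8sia2 (−6.05 ± 0.18, adjusted p = 2.22e-11), the RNA-binding protein gene Mex3a (−5.54 ± 0.15, adjusted p = 1.21e-11) and the kinase gene Stk32b (−5.08 ± 0.18, adjusted p = 6.71e-11) fell next. Fold changes of genes near the floor, Mobp and Hkdc1 among them, depend on the pseudocount of 0.5 CPM and are understated by it.

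Growth and progenitor genes were lower at P14. All 22 immature neuron genes fell (median −2.79, camera adjusted p = 9.77e-12, adjusted p = 0.190 with an estimated correlation). Cd24a, a cell surface glycoprotein gene, fell from 1080.4 ± 18.4 to 44.7 ± 8.41 scaled CPM and the transcription factor gene Sox11 by 4.53 ± 0.12 on the log2 scale. Of 21 axon guidance genes 17 fell and 1 rose (camera adjusted p = 1.01e-04, adjusted p = 0.355 with an estimated correlation). Cntn2, a cell adhesion gene, fell from 1137 ± 52.1 to 102 ± 15.9 and L1cam fell (−1.76 ± 0.10), while Nrcam was the member that rose (0.38 ± 0.10, adjusted p = 0.00357). Without P0 replicate 4 or without P14 replicate 2, 2 axon guidance genes rose. Of 16 progenitor and cell cycle genes 14 fell and 1 rose (camera adjusted p = 3.36e-05, adjusted p = 0.253 with an estimated correlation). Top2a (−3.68 ± 0.22) and Mcm2 (−1.89 ± 0.11), genes of DNA replication, fell. The member that rose was Btg2 (0.89 ± 0.26, adjusted p = 0.00828), an antiproliferative gene that is also on the immediate-early list. Imprinted and growth genes fell in 10 of 13 cases and rose in 2 (camera adjusted p = 0.00166, adjusted p = 0.190 with an estimated correlation). H19 (−5.01 ± 0.20) and the RNA-binding protein gene Igf2bp1 (−5.05 ± 0.18) fell and Peg3 rose (1.47 ± 0.10). Of 20 gamma protocadherin genes, which encode cell adhesion proteins from 1 cluster with shared exons, 19 fell and 0 rose (camera adjusted p = 1.66e-05, adjusted p = 0.383 with an estimated correlation), and 1 rose without P14 replicate 2. Pcdhgb7 fell by 2.39 on the log2 scale.

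Synaptic and channel genes were higher at P14. Of 22 presynaptic genes 21 rose and 0 fell (median 1.15, camera adjusted p = 1.27e-06, adjusted p = 0.355 with an estimated correlation). The list median of P14 replicate 2 was below those of the other P14 libraries. Snap25, a protein of vesicle fusion, rose from 283 ± 17.4 to 1436 ± 106 scaled CPM and Syn2, a synapsin, by 2.34 ± 0.12 on the log2 scale. Of 20 postsynaptic genes 14 rose and 3 fell (camera adjusted p = 0.00166, adjusted p = 0.369 with an estimated correlation). Camk2a, a kinase of the postsynaptic density, went from 119 ± 17.4 to 1060.2 ± 131 and Ddn, dendrin, rose by 2.96 ± 0.11. Voltage-gated channel genes rose in 18 of 24 cases and fell in 3 (camera adjusted p = 6.60e-04, adjusted p = 0.369 with an estimated correlation). The sodium channel subunit gene Scn4b went from 1.14 ± 0.264 to 50.9 ± 7.37, and the calcium channel gene Cacna1h fell (−0.96 ± 0.10). Of 13 genes of GABA-A receptors and chloride transport 9 rose and 0 fell (camera adjusted p = 0.00482, adjusted p = 0.355 with an estimated correlation). Gabrd, the delta subunit, went from 6.31 ± 0.951 to 98.2 ± 9.09, Gabra4 rose by 2.71 ± 0.12, and Slc12a5, the chloride exporter KCC2, went from 115 ± 13.4 to 421 ± 12.3 (1.87 ± 0.10). Glutamate receptor genes rose in 11 of 19 cases and fell in 3, and the list did not pass (camera adjusted p = 0.0589). It passed with DESeq2 (0.0316), with quantile normalization (0.042) and without P14 replicate 4 (0.0493). The NMDA receptor gene Grin2a rose from 17.2 ± 2.24 to 248 ± 20.4 and Gria3 rose (1.87 ± 0.17), while the kainate receptor gene Grik3 fell (−1.26 ± 0.22). Of 18 immediate-early genes, which are transcribed within minutes of neuronal activity, 12 rose and 3 fell (median 2.02, camera adjusted p = 0.0196, adjusted p = 0.490 with an estimated correlation). Arc rose from 2.96 ± 0.566 to 57.3 ± 21.7 and Egr4 by 4.13 ± 0.24, while Fosl2 fell (−1.59 ± 0.24) and had its lowest P14 level, 17.7, in P14 replicate 2. The call of this list was lost on the deposited values without rescaling (0.0905).

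Markers of excitatory neurons did not all move alike. Of 17 markers 10 fell and 2 rose (camera adjusted p = 0.0194, adjusted p = 0.355 with an estimated correlation). Slc17a7, the vesicular glutamate transporter VGLUT1, rose from 129 ± 14.1 to 1444 ± 412 scaled CPM (adjusted p = 3.87e-09) and was lowest at P14 in replicate 2 (833). Nrn1, neuritin, also rose (3.52 ± 0.12, adjusted p = 6.71e-11). Markers of other cell types moved apart. All 10 oligodendrocyte markers rose (median 3.21, camera adjusted p = 3.36e-05, adjusted p = 0.355 with an estimated correlation). Mag, a myelin glycoprotein gene, rose by 4.98 ± 0.18. Of 8 markers of oligodendrocyte precursors 3 rose and 3 fell (camera adjusted p = 0.986). Bcas1 rose (3.77 ± 0.13) and Vcan fell (−3.04 ± 0.14), and the list's median of −0.02 had the opposite sign to its mean of 0.15 and turned positive with 5 other scalings. Microglia markers rose in 9 of 10 cases and fell in 0 (camera adjusted p = 0.00331, adjusted p = 0.369 with an estimated correlation), among them Ctss (1.42 ± 0.17) and P2ry12 (2.10 ± 0.26). Their P14 median was lowest in replicate 2. Of 12 astrocyte markers 8 rose and 0 fell (camera adjusted p = 0.0255, adjusted p = 0.516 with an estimated correlation). The glutamate transporter gene Slc1a2 (3.16 ± 0.12) and S100b (4.80 ± 0.24) were among them. The astrocyte call was lost without P0 replicate 1 (0.0503), without P14 replicate 1 (0.0533, with 7 rising and 2 falling) and on the deposited values (0.0604). Vascular markers fell in 10 of 12 cases and rose in 0 (median −2.93, camera adjusted p = 6.98e-04, adjusted p = 0.377 with an estimated correlation). Their median at P14 was lowest in replicate 2. Cldn5, a tight junction gene of blood vessels, fell from 226 ± 20.4 to 18.7 ± 6.17 and Pdgfrb, a gene of pericytes, fell as well (−2.88 ± 0.18). Of 16 inhibitory neuron markers 9 fell and 2 rose (camera adjusted p = 0.0810), or 4 rose without P14 replicate 2. Lhx6, an interneuron transcription factor, fell (−2.78 ± 0.15) and Pvalb, parvalbumin, went from 0.0743 ± 0.103 to 8.47 ± 1.51 (adjusted p = 4.94e-10). This list passed without P14 replicate 1 (0.0329) and on the deposited values (0.0324).

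Lists of ribosomal proteins, chromatin, nuclear oxidative phosphorylation genes and cholesterol synthesis also passed with the preset correlation. The mitochondrially encoded and matrix lists did not. Of 94 genes named as ribosomal proteins 82 fell and 6 rose (median −1.17, camera adjusted p = 8.47e-15, adjusted p = 0.345 with an estimated correlation). The name prefix also takes in 9 genes of ribosomal S6 kinases, which phosphorylate proteins and are not part of the ribosome. Of these 4 rose, Rps6kb2 among them (1.46 ± 0.30), and 3 fell. Of the other 85 genes 79 fell and 2 rose, a split made after the values were seen. Nuclear genes of oxidative phosphorylation rose in 21 of 23 cases and fell in 0 (camera adjusted p = 2.23e-04, adjusted p = 0.377 with an estimated correlation). Ndufa4 rose by 0.87 ± 0.09. Of 7 tested genes encoded on the mitochondrial genome 6 rose and 0 fell, and the list did not pass (camera adjusted p = 0.0655) except without P0 replicate 2 (0.0165). Its member mt-Co1 went from 118 ± 28.4 to 187 ± 26.8 (0.68 ± 0.16, adjusted p = 0.00157). The mitochondrial genome lies outside the nucleus, and how these reads entered libraries of purified nuclei was not tested. Cholesterol synthesis genes fell in 13 of 16 cases and rose in 0 (camera adjusted p = 9.32e-04, adjusted p = 0.369 with an estimated correlation), Cyp51 among them (−1.56 ± 0.08). Of 25 genes of chromatin and DNA methylation 15 fell and 5 rose (camera adjusted p = 0.0330, adjusted p = 0.345 with an estimated correlation). The maintenance methyltransferase gene Dnmt1 fell (−1.49 ± 0.09). The deacetylase gene Hdac11 rose (1.52 ± 0.09) and was lowest at P14 in replicate 2 (105 scaled CPM). Nuclear long noncoding RNAs rose in 7 of 10 cases and fell in 2 (camera adjusted p = 0.0970), or 5 and 2 without P14 replicate 2, whose list median was the highest at P14. Snhg11 rose (4.57 ± 0.30) and so did Meg3 (2.35 ± 0.30). Of 12 genes of the perineuronal matrix 4 rose and 5 fell (camera adjusted p = 0.327), among them Hapln1 (3.45 ± 0.27) and Tnc (−3.49 ± 0.15). Of 41 collagen genes 17 rose and 12 fell (camera adjusted p = 0.456), among them Col6a1 (3.55 ± 0.17) and Col4a2 (−1.96 ± 0.18). Of 359 Zfp zinc finger genes 87 rose and 135 fell (camera adjusted p = 0.117), or 85 and 131 adjusted over the list alone. The balance was the opposite on the deposited values, with 160 rising and 63 falling. Zfp831 was at 4.90 ± 0.19 and Zfp558 at −3.61 ± 0.16, and the list passed without P0 replicate 4 (0.0361). The median of the collagens changed sign with quantile normalization, and those of the perineuronal and Zfp lists on the deposited values. Adjusted over the list alone, 8 nuclear long noncoding RNAs rose and 2 fell. Apart from these, the Zfp genes and the histone variants, each list gave the same counts either way.

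Of the 29 lists, 20 passed camera with its preset correlation of 0.01 (9 higher, 11 lower at P14). With a correlation estimated from the libraries 0 passed, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.19. A rotation test of each list on its own (fry) called 28. It asks whether the members changed at all and sets them against no other genes. With 68.9% of all tested genes called in this step, a list can pass it without differing from other genes. On the deposited values without rescaling, 11685 genes changed and 72.7% of them were higher at P14, because the median of all genes moved by 0.47.

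**Figure D3:**
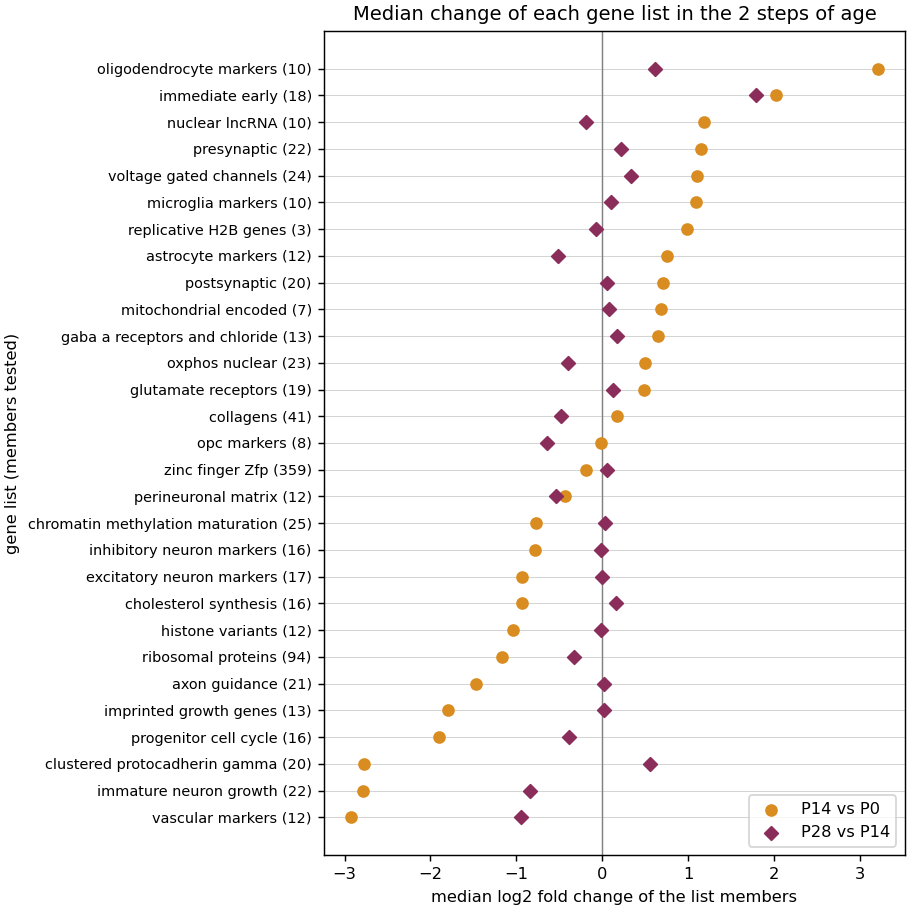
Median log2 fold change of the tested members of each of 29 gene lists (horizontal axis), with circles for P14 against P0 and diamonds for P28 against P14, and lists on the vertical axis with their member numbers. The oligodendrocyte list (3.21) and the vascular list (−2.93) mark the ends of the P14 against P0 medians. Medians near 0 change sign with the scaling: in P14 against P0 those of the precursor, collagen, perineuronal and Zfp lists, and in P28 against P14 those of the axon guidance, cholesterol, chromatin, GABA-A, glutamate receptor, imprinted, microglia, mitochondrial, postsynaptic and Zfp lists.

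Between P14 and P28 all 18 immediate-early genes rose and 18 of 22 immature neuron genes fell, all 22 of which had fallen in the earlier step. Both lists passed camera with the preset correlation, and 0 of the 29 lists passed with an estimated correlation in this step. Arc, an activity-induced gene of synaptic plasticity (ENSMUSG00000022602, chromosome 15, 74669081 to 74672570), rose from 57.3 ± 21.7 to 630.5 ± 228 scaled CPM (3.47 ± 0.27, adjusted p = 9.92e-06). Mkrn3, an imprinted gene of a RING finger protein (ENSMUSG00000070527, chromosome 7, 62417593 to 62420153), fell from 20.7 ± 2.44 to 1.33 ± 0.549 (−3.59 ± 0.22, adjusted p = 1.14e-06). Changes were fewer and smaller than in the earlier step, with 2881 genes changed, 1450 rising and 1431 falling. Of these 221 rose and 227 fell at least 2-fold, and 13 and 9 at least 4-fold. The count was 1920, 1873, 1801 and 1784 without P28 replicates 1, 2, 3 and 4 in turn, and 6466 when libraries were weighted by their spread, a setting chosen after the data were seen.

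The other largest rises were those of the immediate-early transcription factor genes Egr2 (2.86 ± 0.33, adjusted p = 1.72e-04), Junb (2.84 ± 0.20, adjusted p = 4.48e-06), Egr3 (2.63 ± 0.59, adjusted p = 0.00891) and Fosb (2.24 ± 0.34, adjusted p = 9.13e-04), and of Hapln4, a link protein of the perineuronal matrix (12.3 ± 3.57 to 65.4 ± 9.79 scaled CPM, adjusted p = 4.99e-05). Egr3 and Fosb were highest in P28 replicate 1, at 129 and 57.2 scaled CPM. The other largest falls were those of Eln, elastin (174 ± 161 to 21.6 ± 19.8, adjusted p = 0.00606), the matrix protein gene Tnc (−2.59 ± 0.15, adjusted p = 1.14e-06) and Cd24a (−2.12 ± 0.12, adjusted p = 8.09e-07). Lars2, the mitochondrial leucyl-tRNA synthetase, fell from 211 ± 39.0 to 54.7 ± 6.38 (adjusted p = 3.38e-04). The endothelial gene Cd93 (−1.91 ± 0.39, adjusted p = 0.00558) fell too, and had its lowest P14 level, 4.12, in replicate 2. Dlk1, an imprinted gene, went from 12.1 ± 1.85 at P0 to 1.42 ± 0.794 at P14 and 7.91 ± 4.26 at P28.

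All 18 immediate-early genes rose from P14 to P28 (median 1.78, camera adjusted p = 3.70e-17, adjusted p = 0.0910 with an estimated correlation), and 17 rose without P14 replicate 2. Dusp1, a phosphatase gene, rose by 1.83 ± 0.14. Voltage-gated channel genes rose in 10 of 24 cases and fell in 0 (camera adjusted p = 5.82e-06, adjusted p = 0.446 with an estimated correlation), or 12 and 0 adjusted over the list alone. Scn4b (1.05 ± 0.14) was among them. Of 22 presynaptic genes 4 rose and 0 fell (camera adjusted p = 0.00742, adjusted p = 0.769 with an estimated correlation). Vamp1, a vesicle protein gene, was among those that rose (1.05 ± 0.12). The presynaptic call was lost without P14 replicate 2 (0.187), where 4 rose and 2 fell. Without P0 replicate 2, P14 replicate 4 or P28 replicates 2, 3 or 4, 2 genes rose. Of 20 postsynaptic genes 7 rose and 1 fell (camera adjusted p = 0.0546), or 9 and 3 adjusted over the list alone, with a rise of Ddn (0.89 ± 0.11). That list passed with edgeR (0.0424), with DESeq2 (0.00629) and without P14 replicates 1, 3 or 4 or P28 replicates 2 or 3 (0.0298 to 0.0492). Without P14 replicate 2 it did not (0.496), and 7 rose and 3 fell. There were 4 rises and 5 falls on the deposited values, where the median of 0.06 became −0.14. Glutamate receptor genes rose in 4 of 19 cases, Grin1 among them (0.71 ± 0.13), and fell in 0 (camera adjusted p = 0.146), or 4 and 1 without P14 replicate 2 and 3 and 2 on the deposited values. Of 13 GABA-A and chloride genes 2 rose and 0 fell (camera adjusted p = 0.727), or 1 and 0 adjusted over the list alone. Without P14 replicate 2 these were 2 and 3, and on the deposited values 0 and 4. Without P28 replicate 1 or 4 there were 0 rises, and without 7 of the other libraries 1. Slc12a5 rose by 0.36 ± 0.10 (adjusted p = 0.0229), a call lost in 4 of 30 alternatives (range 8.39e-04 to 0.218): without P28 replicate 1, without P28 replicate 4, with the replicate block and on the deposited values. The 20 gamma protocadherin genes had a median of 0.56 and passed as a list (camera adjusted p = 0.0134, adjusted p = 0.876 with an estimated correlation) with 0 members called, or 2 rising without P14 replicate 3. The call was lost without P14 replicate 2 (0.558, 1 rising), with edgeR (0.0507) and with DESeq2 (0.128).

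**Figure D4:**
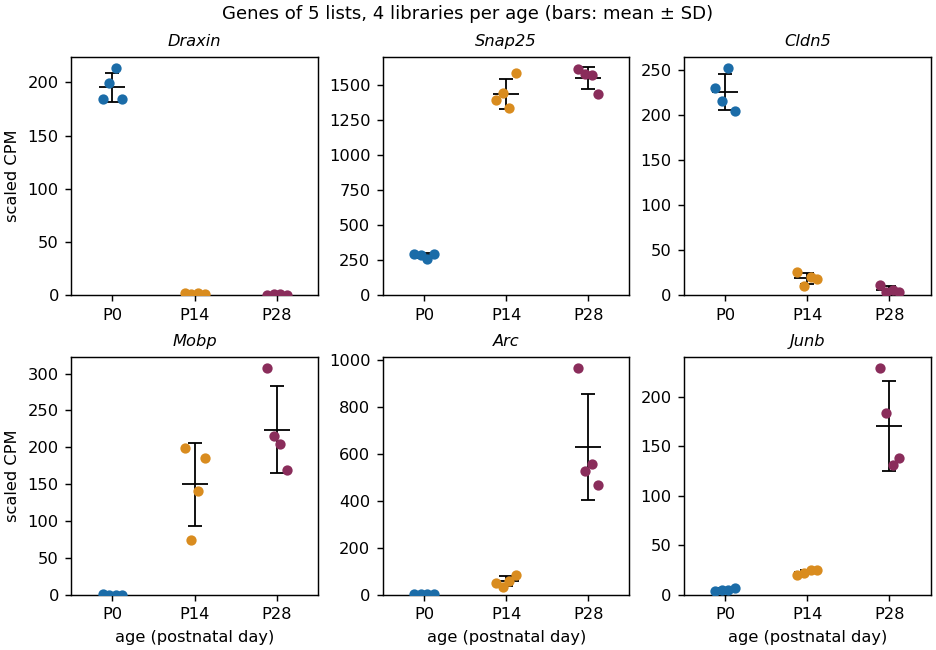
Scaled CPM (vertical axes, linear, from 0) of 6 genes from 5 lists at P0, P14 and P28 (horizontal axes), with 1 point per library and bars for the mean ± SD of 4 libraries. Draxin and Cldn5 are high at P0 and low later, Snap25 and Mobp rise between P0 and P14, and Arc and Junb are highest at P28, with Arc at 968 in P28 replicate 1.

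Of 22 immature neuron genes 18 fell and 0 rose (median −0.84, camera adjusted p = 3.70e-17, adjusted p = 0.0877 with an estimated correlation), or 19 and 0 adjusted over the list alone. Marcksl1 fell by 1.68. Ribosomal protein genes fell in 46 of 94 cases and rose in 0 (median −0.33, camera adjusted p = 1.05e-11, adjusted p = 0.446 with an estimated correlation), or 56 and 1 adjusted over the list alone and 51 and 1 without P14 replicate 2. Rps14 (−0.79 ± 0.10) and Rpl18 (−0.67 ± 0.09) were among them. Of 23 nuclear genes of oxidative phosphorylation 13 fell and 0 rose (camera adjusted p = 5.82e-06, adjusted p = 0.446 with an estimated correlation), or 13 and 1 adjusted over the list alone and also without P14 replicate 2. These included Atp5e (−1.02 ± 0.11) and Ndufa4 (−0.70 ± 0.09), the latter a gene that had risen in the earlier step. Of the 7 mitochondrially encoded genes 0 changed (camera adjusted p = 0.982). Collagen genes fell in 15 of 41 cases and rose in 1 (camera adjusted p = 0.00173, adjusted p = 0.446 with an estimated correlation), or 17 and 3 adjusted over the list alone. Col9a3 fell by 1.64 ± 0.27. Without P28 replicates 2 and 3 in turn the collagen falls numbered 9 and 10, and without P14 replicate 2 there were 16 falls and 5 rises. The collagen rises numbered 0 without P28 replicate 1, 3 or 4. Col12a1 rose (0.61 ± 0.16, adjusted p = 0.0203), a call lost in 4 of 30 alternatives (range 0.0011 to 0.0737): without P28 replicate 1, 3 or 4 and on the deposited values. Of 12 perineuronal genes 6 fell and 2 rose (camera adjusted p = 0.0314, adjusted p = 0.446 with an estimated correlation), a call lost without P14 replicate 1 (0.0921) or 3 (0.063) and on the deposited values (0.168). Progenitor genes fell in 3 of 16 cases and rose in 1 (camera adjusted p = 0.0198, adjusted p = 0.446 with an estimated correlation), with Top2a at −1.62 ± 0.22 and Btg2 at 1.83 ± 0.26. That call was lost without P14 replicate 1 (0.0849) and on the deposited values (0.0902), and 5 fell without P14 replicate 2.

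Among other cell types, 3 of 10 oligodendrocyte markers rose and 0 fell (camera adjusted p = 0.00616, adjusted p = 0.600 with an estimated correlation), and the call was lost without P14 replicate 2 (0.0816). Mal, a myelin gene, rose from 40.0 ± 19.1 to 157 ± 34.4 scaled CPM (adjusted p = 0.00143) and Opalin, listed at 0 in the P0 libraries, rose as well (1.38 ± 0.24, adjusted p = 0.00202). Of 8 precursor markers 4 fell and 0 rose (camera adjusted p = 0.0134, adjusted p = 0.446 with an estimated correlation), or 5 and 0 adjusted over the list alone. Vcan (−1.30 ± 0.14) and Cspg4 (−1.08 ± 0.17) were among them, and the call was lost without P14 replicate 1 (0.0678). Vascular markers fell in 4 of 12 cases and rose in 0 (camera adjusted p = 0.00173, adjusted p = 0.600 with an estimated correlation), or 5 and 0 adjusted over the list alone. The count was 10 without P14 replicate 2 and 2 without P14 replicates 1 or 3 or P28 replicates 1 or 2. Cldn5 went from 18.7 ± 6.17 to 6.19 ± 3.77 (adjusted p = 0.00425) and Pdgfrb fell (−1.14 ± 0.18). Of 12 astrocyte markers 3 fell and 0 rose (camera adjusted p = 0.0314, adjusted p = 0.769 with an estimated correlation), or 8 and 1 adjusted over the list alone. Of these markers 9 fell without P14 replicate 2, and 1 fell without P14 replicate 1 or 3 or P28 replicate 2 or 3. The list's call was lost without P14 replicate 1 (0.228) or 3 (0.0806) and on the deposited values (0.149). The growth factor receptor gene Fgfr3 fell (−1.02 ± 0.21), and Slc1a3 (−0.84 ± 0.23, adjusted p = 0.0245) did not pass in 6 of 30 alternatives (range 1.96e-04 to 0.0742): without P14 replicate 1 or 3 or P28 replicate 2 or 3, without both merged libraries, and with the genes of the 2 tables compared. Of 10 microglia markers 0 changed (camera adjusted p = 0.693), or 1 fell without P14 replicate 2.

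The other lists did not pass in this step. Of 17 excitatory markers 1 rose and 1 fell (camera adjusted p = 0.982), the rise being that of Nrn1 (0.41 ± 0.12, adjusted p = 0.0346) and the fall that of Bhlhe22 (−0.76 ± 0.12). The rise of Nrn1 was lost in 10 of 30 alternatives (range 0.00664 to 0.221), among them the fits without P14 replicate 1 or P28 replicate 1, 2 or 3. Of the markers 4 rose and 2 fell without P14 replicate 2, and 0 to 4 rose when libraries were left out in turn. Of 16 inhibitory markers 1 rose, Pvalb (1.11 ± 0.18), and 1 fell (camera adjusted p = 0.982). The fall was lost in 8 of the 12 fits that left out 1 library, and 2 rose without P0 replicate 4. Of 21 axon guidance genes 1 rose, Cntn2 (0.77 ± 0.11), and 3 fell (camera adjusted p = 0.982), with 0 to 5 falling when libraries were left out in turn, and 2 rising and 5 falling without P14 replicate 2. Of 25 chromatin genes 3 rose and 3 fell (camera adjusted p = 0.982), or 4 and 3 adjusted over the list alone. Ezh1 was higher (0.62 ± 0.08) and the DNA methyltransferase gene Dnmt3a lower (−0.64 ± 0.12). Of 16 cholesterol genes 4 rose and 2 fell (camera adjusted p = 0.350), with 1 to 4 rising and 1 to 3 falling when libraries were left out in turn. Of 13 imprinted and growth genes 3 rose and 1 fell (camera adjusted p = 0.693), or 4 and 4 adjusted over the list alone and 3 and 3 without P14 replicate 2. Over the fits that left out 1 library, 2 to 4 rose and 0 to 3 fell. Of 10 nuclear long noncoding RNAs 1 rose and 1 fell (camera adjusted p = 0.693), and of 3 H2B genes 0 changed (camera adjusted p = 0.982), or 1 rose adjusted over the list alone. Of 359 Zfp genes 27 rose and 14 fell (camera adjusted p = 0.419) or 19 and 9 adjusted over the list alone. The Zfp rises numbered 12 to 43 and the falls 5 to 20 when libraries were left out in turn, and 43 rose and 19 fell without P14 replicate 2. The counts of rising and falling genes on the deposited values were 8 and 63 for the Zfp list, 1 and 8 for chromatin, 0 and 6 for excitatory markers, 1 and 3 for inhibitory markers, 1 and 3 for cholesterol, 3 and 4 for imprinted and growth genes and 0 and 3 for histone variants. Cholesterol genes (1 and 2) and histone variants (1 and 2) also fell more often than they rose with scaling to the library total and with quantile normalization. Of the 29 lists 14 passed camera with its preset correlation (5 higher, 9 lower at P28). With an estimated correlation 0 passed, where 2 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0877. The rotation test called 10. On the deposited values without rescaling 4530 genes changed and 14.8% of them were higher at P28, beside a shift of −0.20 in the median of all genes.

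Over the whole span from P0 to P28 the direction of the largest changes was that of the earlier step. Mobp (224 ± 59.2 scaled CPM at P28, 8.43 ± 0.30, adjusted p = 4.52e-11), Arc (7.47 ± 0.27, adjusted p = 4.61e-11) and Lamp5 (6.53 ± 0.17, adjusted p = 3.26e-12) rose most. Igfbpl1 (−7.86 ± 0.18, adjusted p = 1.07e-12), Draxin (−7.33 ± 0.15, adjusted p = 7.84e-13) and Trim67 (−7.33 ± 0.16, adjusted p = 1.07e-12) fell most. In all, 11207 genes changed, 5610 rising and 5597 falling. All 22 immature neuron genes fell (camera adjusted p = 2.71e-13, adjusted p = 0.187 with an estimated correlation), as did 84 of 94 ribosomal protein genes while 5 rose (camera adjusted p = 7.06e-17, adjusted p = 0.289 with an estimated correlation). All 10 oligodendrocyte markers rose (camera adjusted p = 1.71e-05, adjusted p = 0.305 with an estimated correlation). Of 22 presynaptic genes 21 rose and 1 fell (camera adjusted p = 4.19e-07, adjusted p = 0.322 with an estimated correlation), or 0 fell without P0 replicate 2 or 4. In this span 15 of 18 immediate-early genes rose and 2 fell (camera adjusted p = 2.11e-05, adjusted p = 0.305 with an estimated correlation). Imprinted and growth genes fell in 8 of 13 cases and rose in 2 (camera adjusted p = 0.00951, adjusted p = 0.289 with an estimated correlation), a call lost without any 1 of the 4 P0 libraries (0.0537 to 0.0728). The imprinted counts were 1 to 2 rising and 6 to 9 falling over the fits that left out 1 library. Of the 29 lists 19 passed camera with the preset correlation. With an estimated correlation 0 passed, where 4 had an unadjusted p under 0.05 and the lowest adjusted p was 0.187. The rotation test, which sets a list against no other genes, called 27 where 71.2% of all tested genes were called. On the deposited values without rescaling 11303 genes changed and 63.2% of them were higher at P28, with the median of all genes at 0.27.

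Of the genes called in both steps, 678 rose in each and 730 fell in each, while 371 rose to P14 and then fell and 381 fell to P14 and then rose. Without P14 replicate 2 the first 2 counts were 996 and 1137. Both steps share the P14 libraries, so an error in those libraries pushes the 2 steps in opposite directions. In 20 simulations in which no gene changed with age, 0 genes turned in either way. Few genes should pass the threshold in such data, so these runs do not cover genes that changed in 1 step only. Independent lists of the same sizes would share 492 and 501 genes of the turning kinds. For genes that rose in each step or fell in each step they would share 499 and 494. When the P14 libraries were divided between the steps in 6 ways, the turning counts were 75 to 465 and 48 to 413, and without P14 replicate 2 they were 527 and 514. Over the same 6 divisions 193 to 1280 genes rose in each step and 151 to 1310 fell in each. These divisions leave fewer P14 libraries to a step than the main fit. The total of 752 turning genes was 464, 484, 459 and 452 without P28 replicates 1, 2, 3 and 4 and 496 without P14 replicate 4. Eln, which fell to P28, was at 41.9 ± 6.41 at P0 and 174 ± 161 at P14, and Dlk1 was lowest at P14.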

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

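The tests of transcript length, GC content and depth in this part were set before their results were seen, and the choice of this library for them came after the libraries were compared. In 434 groups of 4 libraries (145 genes, list medians and read totals at each age, less Opalin at P0, where all 4 values were 0), 33 had a highest or lowest library farther from the others than Dixon's 95% limit for the gap divided by the range. For independent groups not chosen by their values, chance would give about 1 in 20, or 21.7. Many of these genes were chosen by their results in the same libraries, and list medians hold some of them. The 33 is therefore not tested against that number. Of the 33, 15 were in P14 replicate 2, 13 low and 2 high, against 0 to 4 in any other library.

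In P14 replicate 2 the low values, in scaled CPM, were those of Stk32b (1.23, gap ratio 0.871), H3f3a (8.79, gap ratio 0.871), H1f0 (48.1, gap ratio 0.928), P2ry12 (4.69, gap ratio 0.931), Slc17a7 (833, gap ratio 0.882), Fosl2 (17.7, gap ratio 0.878), Hdac11 (105, gap ratio 0.918), Egr3 (1.86, gap ratio 0.925), Cd93 (4.12, gap ratio 0.903) and Dnmt3a (268, gap ratio 0.880). The high value was that of H3f3b (246, gap ratio 0.931). Among list medians on the log2 scale, microglia (2.83, gap ratio 0.845), presynaptic (8.59, gap ratio 0.868) and vascular genes (1.88, gap ratio 0.957) were low and nuclear long noncoding RNAs (8.64, gap ratio 0.928) high.

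P14 replicate 2 differed from the mean of the other P14 libraries with an SD of 0.72 across genes on the log2 scale, against 0.20 to 0.38 for the other 11 libraries. Its greater depth, 33611769 reads, is argued against, since after thinning to the shallowest library its mean r with the other P14 libraries was 0.949, and that of every other library at least 0.974. Loss of long transcripts stays open: the deviation fell with transcript length (Spearman rho −0.26 across genes, with medians of 0.18 in the 25% shortest and −0.25 in the 25% longest transcripts), but rho lay between the bounds set for and against this source, and the other libraries ranged from −0.27 to 0.25. A GC content bias stays open too (rho 0.11, others −0.34 to 0.21), again between its bounds. The genes differ from library to library in ways that RNA quality, nucleus purity or the animal itself could produce, and no biological explanation was tested, as the design names none for a single library.

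In other P14 and P28 libraries, the values far from the rest of their age were those of Pvalb (10.7, gap ratio 0.844) in P14 replicate 4, of Stk32b (2.42, gap ratio 0.836), Egr3 (129, gap ratio 0.840) and Fosb (57.2, gap ratio 0.963) in P28 replicate 1, and of Tnc (2.07, gap ratio 0.860) and Ddx3y (68.7, gap ratio 0.963) in P28 replicate 3. Sox11 (32.4, gap ratio 0.912) and Dnmt3a (249.8, gap ratio 0.861) were highest in P28 replicate 4. The median log2 level of cholesterol synthesis genes was lowest in P28 replicate 1 (6.25, gap ratio 0.854).

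Among the P0 libraries, L1cam was low in replicate 1 (509.8, gap ratio 0.884), where Xist was high (15.9, gap ratio 0.872) and the median log2 level of imprinted and growth genes low (4.93, gap ratio 0.836). Gria3 (125, gap ratio 0.839) and Zfp831 (0.510, gap ratio 0.894) were high in replicate 2. In replicate 4, H2ax (31.0, gap ratio 0.846) was high, Top2a (41.2, gap ratio 0.839) and Igf2bp1 (17.4, gap ratio 0.851) were low, and the median log2 level of immature neuron genes was high (10.12, gap ratio 0.843). The labels give P0 replicate 1 as merged, and its Y-linked genes were read at the level of the other P0 libraries.

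Outside the genes present in all 3 tables, 7 genes had a mean of at least 1 CPM at an age. The largest was Chrnb3, a nicotinic receptor subunit gene, at 1.48 CPM at P14 and 2.995 CPM at P28, which the P0 table does not list. Klk6 went from 0.137 to 1.10 and Cd7 from 0.18 to 1.02 CPM between P14 and P28, and 6 of the 7 were missing from the P0 table. A change from or to the age whose table lacks a gene was not tested, because the gene has no value there. In the fit on the genes of the P14 and P28 tables, 2 of these 6 genes passed the filter on low values. Chrnb3 rose from P14 to P28 (log2 fold change 0.86 ± 0.15, adjusted p = 0.00761), and the other, a gene without a symbol, did not pass (adjusted p = 0.787).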

How the results depend on the processing

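Library weights, leaving out P14 replicates 2 and 4 together, fry and the estimated correlation without P14 replicate 2 were chosen after the data were seen, as was the match of 9 list members by identifier, and the other settings before. The H2bc21 result, no difference that passes at P14 against P0, P28 against P14 or P28 against P0, changed side in 1 case, the deposited values without rescaling (log2 fold change 0.53 at P14 against P0), where the median of all genes moved by 0.47. Its sign, near 0, turned with upper-quartile scaling (−0.009 for P28 against P0), thinned reads (−0.005 for P14 against P0 and −0.096 for P28 against P0) and library weights (−0.031 and −0.088). Without each library in turn it ranged from −0.057 to 0.136 for P14 against P0, −0.134 to 0.005 for P28 against P14 and −0.121 to 0.079 for P28 against P0. Why these signs turned was not tested. Changed genes at P14 against P0 and P28 against P0 stayed within 1.5 times the count of 10848 and 11207, except with a minimum of 2-fold (5178 and 5690), which takes fewer genes by construction. For P28 against P14 (2881) they were 448 with that minimum and 1172 at an adjusted p of 0.01, both by construction, 4530 on the deposited values, 1735 without both merged libraries, 6466 with library weights, and 1784 to 4048 without each library in turn, the last value without P14 replicate 2. The replicate block gave 10632, 2357 and 10987, although the replicate numbers do not pair samples. Genes turning at P14 (752) numbered 65 and 264 with the stricter thresholds, 2025 on the deposited values, 432 without both merged libraries, 1683 with library weights and 452 to 1041 without each library in turn. Fewer samples are left where libraries are taken out, which cannot account for the rises without P14 replicate 2, and the cause of the moves was not tested. List calls went to 0 in each of the 3 comparisons with an estimated correlation, and to 0 again without P14 replicate 2.

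Among 153 named gene results, 142 of them called, 4495 of 4577 alternative values kept direction and side, 51 fell short of the threshold, 18 newly passed and 13 reversed, 2 of them of called genes. On the deposited values those were Macroh2a1 (0.04) and H2bu2 (0.036) at P14 against P0, beside H2ax (0.20) at P14 against P0 and H3f3a (−0.16), H2az1 (−0.11) and H2az2 (−0.13) at P28 against P14, where the shift of all genes makes the direction. H3f3a at P28 against P14, 0.04 with all libraries, was −0.102 with edgeR, −0.097 with DESeq2, −0.046 with thinned reads, −0.34 with library weights (adjusted p = 0.00906) and −0.41 without P14 replicates 2 and 4 (adjusted p = 0.0124). Without each library in turn it was −0.355 to 0.203, the lowest without P14 replicate 2, in which it was low (adjusted p = 0.0104). The fall passed with library weights and in the 2 settings without P14 replicate 2. H2az2 was −0.01 to 0.118 without each library in turn, the lowest without P14 replicate 3. For these the cause was not tested. Depth limits H2bc21 to 102 to 402 reads per library. A 1.5-fold change of a gene was found in 25.4 to 31.3% of simulated cases. In each simulated comparison 67 of 15734 genes were changed 1.5-fold, and similar numbers 2-fold and 4-fold. In the data 68.9% and 71.2% of genes changed at P14 and P28 against P0, which makes the adjustment over genes less strict. The simulated share is therefore not the power for H2bc21 in those 2 comparisons.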

Other observations

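The genes and tests of this part were chosen after the results were seen, apart from the test of long genes, which was set before. Mkrn3, an imprinted gene on chromosome 7 (62417593 to 62420153), was at 18.2 ± 2.21 scaled CPM at P0, 20.7 ± 2.44 at P14 and 1.33 ± 0.549 at P28, and its fall from P14 to P28 (log2 fold change −3.59 ± 0.22, adjusted p = 1.14e-06) was among the largest of that step. In 2 imprinted neighbours the change of that step did not pass the test, which does not show that it was absent there. Ndn was at 280.1 ± 24.8, 157 ± 12.3 and 169.8 ± 68.6 scaled CPM, with a log2 fold change of 0.02 ± 0.23 from P14 to P28 (adjusted p = 0.95). Magel2 was at 14.6 ± 1.97, 8.05 ± 4.23 and 4.97 ± 0.943 (−0.52 ± 0.29, adjusted p = 0.222). The difference between the 3 genes was not itself tested.

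Of the genes that rose to P14 and fell to P28, Hapln1, Eln, Myoc, Lct, Htra1, Mertk, Slc7a10 and Atp13a4 were among those with the largest smaller step, and of those that fell and then rose Dlk1, Sik1, Dusp4 and Prag1. Mertk, a phagocytosis receptor gene, had log2 fold changes of 2.23 ± 0.26 and −1.27 ± 0.26 (adjusted p = 5.28e-06 and 0.00552 for the 2 steps). Slc7a10, an amino acid transporter gene, was at 3.04 ± 0.252, 13.3 ± 2.46 and 5.26 ± 1.07 scaled CPM at P0, P14 and P28 (adjusted p = 2.67e-07 and 4.32e-04). Sik1, a salt-inducible kinase gene, went the other way, with 49.7 ± 8.50, 10.9 ± 2.39 and 31.3 ± 7.63 (adjusted p = 4.28e-07 and 4.09e-04). Whether the turning genes changed in the selected neurons or in other cells was not tested. The astrocyte list also turned, with median log2 fold changes of 0.75 and −0.52 in the 2 steps. Its median log2 level ran from 5.74 to 7.11 between the P14 libraries.

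Oligodendrocyte markers rose with age in nuclei selected for a Cre line of excitatory neurons, at a median of 3.21 (quartiles 2.30 and 4.87) on the log2 scale from P0 to P14. A lower share of selected nuclei that raised every other cell type alike is argued against by the list medians. The vascular median was −2.93 (quartiles −3.31 and −2.48) and the inhibitory median −0.78, beside 0.75 for astrocytes and 1.09 for microglia. Whether a lower share let in other cell types in unequal amounts cannot be decided from these medians, since that would allow some lists to fall. Oligodendrocyte RNA or nuclei carried along in varying amounts were not excluded, and the markers moved together between the libraries of an age. Their deviations had a mean pairwise correlation of 0.852 within P14 and P28 (0.885 without P14 replicate 2). In 1000 random gene sets the median was −0.022 and the 95th percentile 0.201. Random sets do not show what other lists of related genes give. The inter-gene correlation estimated for camera over all 12 libraries was 0.613 for the oligodendrocyte list. It was 0.877 for gamma protocadherins, 0.555 for presynaptic genes and 0.015 for glutamate receptors. Moving together therefore does not single out carried-over RNA. A correlation does not show that the markers kept a single ratio. Affinity selection of tagged nuclei should remove these cells. Growth of the oligodendrocyte population with age is not excluded by these values and was not tested.

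All 18 immediate-early genes rose from P14 to P28, and a low level in P14 replicate 2 as the whole source is argued against, since 17 rose without it. Handling or the collection day of the P28 pups stays open, since 0 of the deposited tables hold libraries of more than 1 age. The labels of 3 of the 4 P28 libraries share a stamp of 6 digits, and what it stands for is not given in the sources used here. P28 replicate 1 held the highest level of Arc (968 scaled CPM, against 469 to 559 in the other P28 libraries). A change in neuronal activity with age stays open and was not tested.

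Whether long genes took another share of expression with age was tested by the Spearman rho of level with gene span across genes. It was 0.211 ± 0.017 at P0 and 0.188 ± 0.008 at P28 (mean ± SD, n = 4), with an exact two-sided permutation p of 0.086, where the smallest possible p is 0.029. The ranges of 0.19 to 0.228 and 0.18 to 0.196 overlap through P0 replicate 1. An overlap of ranges had been set in advance as evidence against a change, but 4 libraries whose ranges overlap by 1 value do not show that 2 groups are alike, so the question stays open.

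Other groupings of the same libraries were tried for each comparison of 8 libraries, in 35 splits. Only the real split gave as many changed genes, which is 1 of 35 in each comparison and the smallest share possible. Every other split put both ages in each group, which widens the spread within groups and lowers the counts. Age also coincides with the deposited table in the real split. The splits therefore cannot tell an age difference from a table difference, and no source is concluded from them. The real counts were 10848, 2881 and 11207, and the highest of the other splits were 5 for P14 against P0, 14 for P28 against P14 and 0 for P28 against P0.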
